A study of Mus musculus with 6 samples.

How the data were processed

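The series holds 6 paired-end RNA-seq libraries of sorted mouse cardiac macrophages, 3 from Tet2 KO and 3 from Tet2 WT donor progenitors; the sort gate is not given in the sources used here. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.4 and assigned to the mouse transcriptome (GRCm38) with kallisto 0.44.0, which divides reads shared between transcripts by a model. Per the file headers, the authors deposited for each transcript an estimated count and a TPM value, with its length and effective length. The estimated counts are not normalized, and the deposited TPM values are scaled within each library to a common total. The annotation release was not given in the sources used here. Of the 118783 transcripts, 116622 (98.2%) matched the mouse GENCODE annotation of GRCm38 by identifier without version, and 99.8% of those had the same length there. The 2161 unmatched transcripts were left out; they held at most 0.67% of the counts of a library. Genes whose reads are shared with near-identical copies depend on how kallisto divided them.

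Estimated counts were summed per gene over 35865 genes and rounded to whole numbers. Genes were kept by edgeR's expression filter (16386), scaled by TMM and tested with edgeR 4.0.16's quasi-likelihood test with robust fitting, in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. CPM values are TMM-normalized, except that summed marker CPM uses each library's own total. Standard errors were derived from the fold change and the F statistic. Gene lists, 35 in all, were fixed before the data were examined and tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, with the correlation estimated per list, and with fry; 33 had the 5 tested members needed. Library totals and marker sums were compared by exact permutation tests over the 20 assignments of labels, whose smallest two-sided p is 0.1. List levels relative to the pan-macrophage markers are differences of mean log2(CPM + 0.5) within each library, leaving out shared genes; this measure was chosen after seeing the data.

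The depth of 37349505 to 55771087 estimated counts per library and the 3 libraries per group set the precision. In data simulated for this comparison over 16056 genes, with 200 changed, the test called 6% of genes changed by 1.5-fold, 50% at 2-fold, 88% at 4-fold and 92% at 8-fold, and 6.35% of its calls were false. These rates hold for 200 changed genes, and the adjusted threshold is looser where more genes change. With no change simulated, 0 of 33 lists were called by camera. Genes were drawn independently there, so this does not test lists whose members vary together. Estimated correlations of the real lists reached 0.98. Other splits of the real libraries, which mixed the genotypes within groups, gave up to 21 called lists. No pair of libraries agreed within sampling noise: the chi-square per gene between libraries of a genotype was at least 70.5.

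The genes named were set by a rule written before the data were examined: Tet2; the 12 largest rises and 12 largest falls among called protein-coding genes with a mean log2 CPM of at least 2 and no overlap between the groups' libraries; up to 4 members of each list described, by smallest p in the list's direction; and 13 genes named whatever their values. Of the falls, 1 gene is not reported here. Members that went against their list, called members of lists that were not called as a whole, Ddx3y, Gsn and Dcn were chosen after their values were seen. The alternatives tried were RLE and upper-quartile scaling, no low-count filter and a stricter filter, each library left out, the replicate number as a block, a GC correction, length-scaled TPM counts, thinning to equal depth, leaving out mitochondrially encoded genes, limma voom with and without library weights, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), and a fold limit of 1.5. Scaling to the pan-macrophage markers, a fibroblast covariate and leaving out Tet2 WT replicate 1 with Tet2 KO replicate 1 were added after seeing the data.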

Results

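RNA was sequenced from cardiac macrophages that had been sorted from digested mouse hearts and that derived from donor haematopoietic progenitor cells. The donors either carried the Tet2 knockout (Tet2 KO) or were wild type for Tet2 (Tet2 WT), on the C57BL/6J strain. Tet2 encodes a dioxygenase that oxidises 5-methylcytosine in DNA, and its loss in blood progenitors is a common form of clonal haematopoiesis. The study concerned the heart in mice whose blood was partly replaced by Tet2-deficient cells without conditioning, and the comparison asks which transcripts differ between macrophages of the 2 genotypes. There were 3 libraries per genotype. The labels do not state that the 3 libraries of a genotype came from separate animals, so the p-values measure the spread between these libraries, which may be technical. The estimated counts per library were 37349505, 53586246 and 55771087 for Tet2 KO and 49883028, 53586473 and 51477060 for Tet2 WT. Of 118783 transcripts listed for each library, between 63076 and 73467 had a count above 0.

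The targeted gene was not lower in the Tet2 KO libraries in the fit reported here. Tet2 (ENSMUSG00000040943.12; GRCm38 chromosome 3, 133463679 to 133545139, minus strand) stood at 80.6 ± 2.23 counts per 1e6 counts (CPM) in Tet2 KO and 64.8 ± 9.91 CPM in Tet2 WT (mean ± SD, n = 3 each). Its log2 fold change was 0.32 ± 0.14 (SE), and the edgeR quasi-likelihood test gave an adjusted p of 0.159. With length-scaled TPM counts Tet2 was called higher (0.43 ± 0.12, edgeR adjusted p = 0.0458), and scaled to the pan-macrophage markers, a scaling chosen after seeing the data, its log2 fold change was -0.38 ± 0.17 (edgeR adjusted p = 0.0726). The main protein-coding transcript, ENSMUST00000098603.7 with 11 exons, was at 6.77, 7.74 and 8.75 transcripts per 1e6 transcripts (TPM) in Tet2 KO and 6.91, 9.29 and 7.81 TPM in Tet2 WT. Of the 10 Tet2 transcripts listed, 4 did not overlap in TPM between the genotypes. ENSMUST00000196398.4 has 1 exon that ENSMUST00000098603.7 lacks (133479342 to 133479365), and the 2 transcripts also differ at both ends. That interval lies within the exon of the retained-intron transcript ENSMUST00000200203.1. ENSMUST00000196398.4 received 688, 617 and 147 estimated counts in Tet2 KO but at most 0.545 in Tet2 WT. These counts cannot be tied to that exon alone. ENSMUST00000197211.1, a retained-intron transcript over the last exons of the gene, received 0 counts in each Tet2 KO library and 30.3, 107 and 6.69 in Tet2 WT. ENSMUST00000197118.4 and ENSMUST00000196292.1, which cover exons at the 5' end, were higher in Tet2 KO, at 10.5, 7.71 and 8.03 against 6.64, 5.85 and 6.06 TPM and at 7.28, 3.59 and 4.90 against 1.79, 3.18 and 3.10 TPM. Tet2 transcripts share sequence, and kallisto divides shared reads between them by a model. The labels do not say which part of Tet2 was deleted, so reads from the rest of the gene do not test the knockout. The other TET genes were not called either: Tet1 had a log2 fold change of -2.08 ± 0.67 (edgeR adjusted p = 0.0651, under 4.3 CPM in each library; called without the low-count filter, at 0.0452) and Tet3 of 0.20 ± 0.25 (edgeR adjusted p = 0.666).

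**Figure D1:**
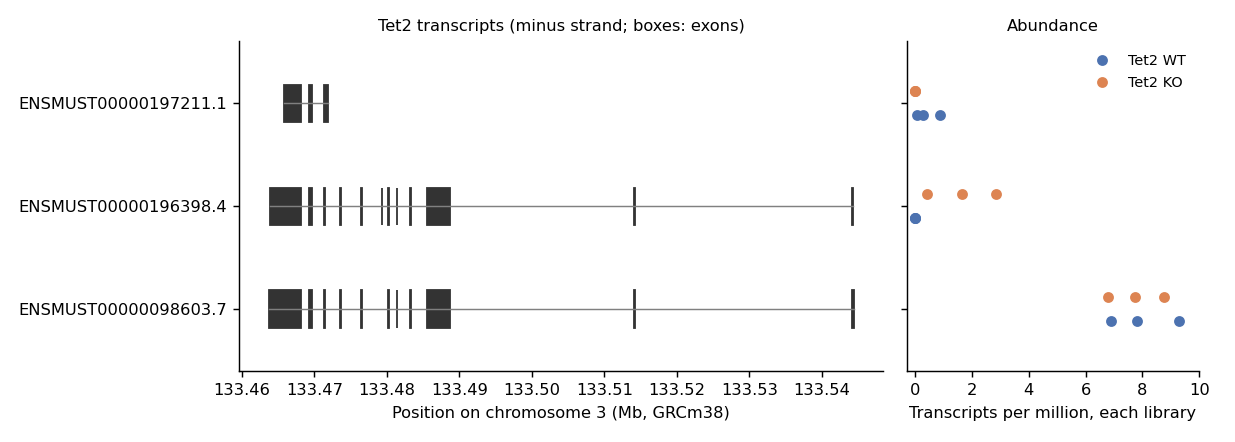
Exons of 3 Tet2 transcripts on chromosome 3 (left, position in Mb) and the abundance of each in TPM (right; 1 point per library, 3 libraries per genotype). ENSMUST00000196398.4 lies above 0.4 TPM in the Tet2 KO libraries and near 0 in Tet2 WT, while ENSMUST00000098603.7 overlaps between the genotypes.

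Of the 33 gene lists tested, the fibroblast markers had the largest median change. All 18 fibroblast markers tested were lower in the Tet2 KO libraries, with a median log2 fold change of -3.03, and all 18 passed when adjusted over the list alone. The collagen genes Col1a1 and Col5a1 had log2 fold changes of -3.33 ± 0.24 and -3.34 ± 0.23 (SE), and Sparc, a matrix-binding glycoprotein, one of -2.65 ± 0.19. Col1a1 stood at 19.4 CPM in Tet2 KO and 195 CPM in Tet2 WT, and Col1a2 at 49.0 and 392 CPM. The 18 markers together made up 3560 ± 1103 CPM in Tet2 KO and 26767 ± 8034 CPM in Tet2 WT, a ratio of 7.52, with no overlap between the groups (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries can give). The camera test of the list gave an adjusted p of 7.83e-23 with the preset correlation and an adjusted p of 0.32 with an estimated correlation.

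Pan-macrophage markers moved the other way and by less. Of 16 tested, 13 were higher in Tet2 KO and 0 lower, with a median log2 fold change of 0.74; adjusted over the list alone, all 16 passed. Adgre1, which encodes the macrophage surface protein F4/80, rose from 780 ± 124 to 1331 ± 153 CPM (log2 fold change 0.77 ± 0.16, edgeR adjusted p = 0.0112). That call was lost without Tet2 KO replicate 3 (edgeR adjusted p = 0.0594). Cd14, the lipopolysaccharide co-receptor, rose by 0.90 ± 0.16 on the log2 scale, the transcription factor Spi1 by 0.74 ± 0.14, the protease gene Ctss by 0.81 ± 0.15 and the Fc receptor Fcgr1 by 0.76 ± 0.16. The summed pan-macrophage markers were 34907 ± 3125 CPM in Tet2 KO and 23827 ± 3629 CPM in Tet2 WT (exact permutation test, two-sided p = 0.1). The camera adjusted p of the list was 7.89e-10, and the adjusted p was 0.32 with an estimated correlation.

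**Figure D2:**
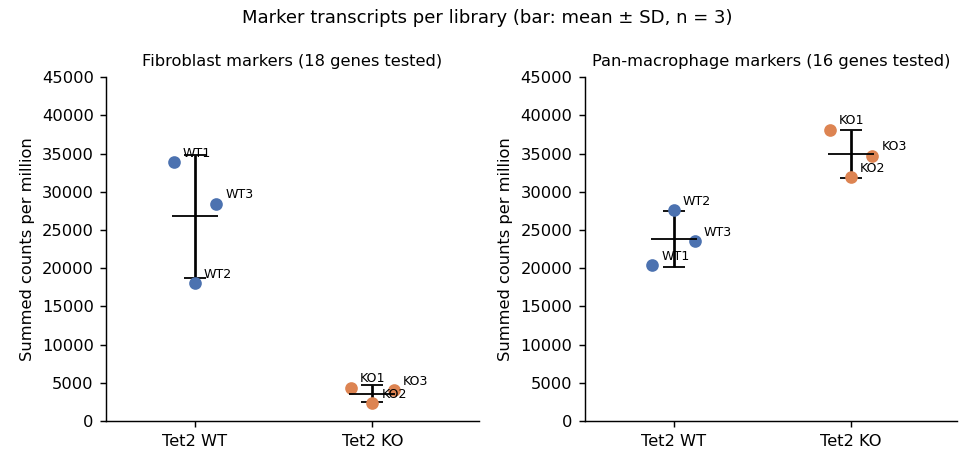
Summed CPM of the fibroblast markers (left) and of the pan-macrophage markers (right) in each library, with the mean and SD of 3 libraries per genotype. The 3 Tet2 WT libraries hold 18035 to 33846 CPM of fibroblast markers and the 3 Tet2 KO libraries 2297 to 4329 CPM, while the pan-macrophage markers are higher in the Tet2 KO libraries.

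Across the transcriptome, 2653 of 16386 tested genes differed between the genotypes at an edgeR adjusted p under 0.05. Of these, 1001 were higher and 1652 lower in Tet2 KO, so that 62.3% were lower. The 3 libraries of each genotype did not overlap for 1000 of the higher and 1651 of the lower genes, and for 34.5% of all tested genes, where chance gives 10%. Rises were small: the median log2 fold change of the higher genes was 0.69 (quartiles 0.58 and 0.85), close to the 0.74 of the pan-macrophage markers. Without Tet2 WT replicate 1 there were 1382 genes and without Tet2 KO replicate 3 there were 1750. The higher genes numbered 350 and 428 in those fits, 595 without Tet2 KO replicate 1 and 608 without Tet2 WT replicate 3. Without Tet2 WT replicate 1 and Tet2 KO replicate 1 together, a fit chosen after seeing the data, 1188 genes differed, 177 of them higher. Limma on log2(TPM + 1) put 83.4% of its 2314 genes lower, and limma on log2(TPM + 0.1) 82.8% of its 2322. Libraries scaled to the pan-macrophage markers, a scaling also chosen after seeing the data, moved the median of all genes by -0.71 on the log2 scale and left 21 of 7620 called genes higher. With each library's fibroblast marker level as a covariate, edgeR called 0 genes, with 649 at an unadjusted p under 0.05. Some genes named below each lost their calls in at least 3 of the 6 fits with a library left out. These were Cxcl16, Ccl6, C1qa, Gpr141, C4b, Slc11a1, Trf, Ly6c1, Eng, Bank1, Ighm, Mbd2, Dnmt3a, Tmem171, Plxnb3 and Plk1. Pycard, Nlrp1a, Traf1, Klf6, Atf3 and Dusp1 did so as well, as given below.

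**Figure D3:**
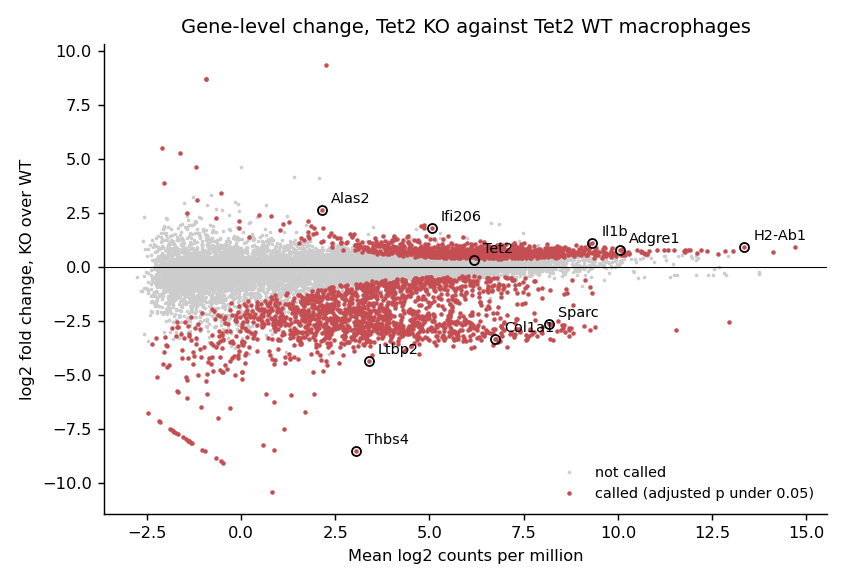
Log2 fold change of Tet2 KO over Tet2 WT against mean log2 CPM for the 16386 tested genes, with the 2653 called genes in red. Called rises form a narrow band with a median of 0.69 and called falls reach further; points beyond about 5 in either direction are genes with almost no counts in 1 genotype, whose fitted value depends on the prior count.

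The 12 largest rises among well-expressed protein-coding genes whose libraries did not overlap included genes of several kinds. Alas2, which catalyses the first step of haem synthesis in erythroid cells, rose most, from 1.21 ± 0.640 to 7.59 ± 1.56 CPM (log2 fold change 2.65 ± 0.43, edgeR adjusted p = 0.00292). The TGF-beta family gene Gdf3 rose from 11.9 ± 1.67 to 46.0 ± 15.1 CPM (1.95 ± 0.24). The interferon-inducible genes Ifi206 and Ifi44 rose by 1.82 ± 0.15 and 1.45 ± 0.29, and Ifi206 went from 14.8 ± 0.765 to 52.0 ± 7.72 CPM. The mitotic genes Kif2c and Plk1 rose by 1.55 ± 0.33 and 1.51 ± 0.35. The other 6 were the class I-like gene H2-M2 (1.92 ± 0.45), the metalloproteinase Mmp25 (1.81 ± 0.40), Tmem171 (1.56 ± 0.42), Parvg (1.44 ± 0.17), the plexin Plxnb3 (1.43 ± 0.37) and Ms4a4c (1.43 ± 0.21). H2-M2 lost its call without the low-count filter (edgeR adjusted p = 0.155), and H2-M2, Tmem171, Plxnb3 and Plk1 each lost it with some single library left out.

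The largest falls included extracellular matrix genes. Thbs4 was at 0, 0 and 0.115 CPM in Tet2 KO and at 3.07, 10.2 and 36.3 CPM in Tet2 WT, so its fitted log2 fold change of -8.51 ± 1.31 rests on almost no Tet2 KO counts. Comp, Ltbp2 and Adamtsl2 encode matrix or matrix-associated proteins. Comp averaged 0.391 CPM in Tet2 KO and 9.28 CPM in Tet2 WT, and Ltbp2 and Adamtsl2 had log2 fold changes of -4.35 ± 0.39 and -4.01 ± 0.41. The transcription factors Sox5 and Zfp423 had -4.42 ± 0.76 and -4.34 ± 1.05. Ece2 (-4.79 ± 1.12), Bcat1 (-4.30 ± 0.98), Peg3 (-4.09 ± 0.43), Rgs17 (-4.05 ± 0.42) and Dlg2 (-3.92 ± 0.66) also fell. In Tet2 WT, Adamtsl2 averaged 49.5 CPM and the other genes named here under 22 CPM. Without the low-count filter Thbs4, Ece2, Comp, Zfp423 and Bcat1 lost their calls (edgeR adjusted p = 0.0590, 0.168, 0.139, 0.176 and 0.130), and limma voom did not call Thbs4 and Comp. Leaving out Tet2 KO replicate 1 ended the calls of Comp and Zfp423 (edgeR adjusted p = 0.0687 and 0.0748). Leaving out Tet2 WT replicate 1 ended those of Ece2, Zfp423 and Bcat1 (edgeR adjusted p = 0.0793, 0.0845 and 0.0605).

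Interferon-responsive and antigen-presentation genes were higher in Tet2 KO. In the type I interferon list, 20 of 31 tested genes rose and 0 fell (25 rose when adjusted over the list alone), with a median log2 fold change of 0.83. Irf7, a master transcription factor of the response, rose from 32.1 to 85.5 CPM (1.42 ± 0.19), and Oas1a, Ifit3 and Phf11b rose by 1.02 ± 0.14, 1.11 ± 0.16 and 0.95 ± 0.14. In the interferon-gamma list 13 of 26 rose and 0 fell (15 adjusted over the list alone; median 0.59), among them the GTPase gene Irgm1 (0.80 ± 0.13), the peptide transporter gene Tap1 (0.84 ± 0.15) and Ifi47 (0.91 ± 0.16). In the MHC class II list 11 of 13 rose and 0 fell (11 adjusted over the list alone; median 0.75). H2-Ab1, a class II beta chain, rose from 7227 ± 1031 to 13724 ± 1634 CPM (0.93 ± 0.18), H2-DMb1 rose by 0.94 ± 0.15, H2-DMb2 by 0.89 ± 0.17 and the class II transactivator Ciita by 0.73 ± 0.15. Camera adjusted p-values were 1.09e-13, 1.66e-08 and 5.83e-08 for the 3 lists, and the adjusted p was 0.32 for each with an estimated correlation. Set against the pan-macrophage markers of the same libraries, the mean log2 level of the 3 lists differed between Tet2 KO and Tet2 WT by 0.04 ± 0.22, -0.17 ± 0.16 and 0.06 ± 0.05 (SE; exact permutation test, two-sided p = 1, 0.5 and 0.3).

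Of 32 cell cycle genes, 21 were called higher, 0 lower and 11 neither (28 higher adjusted over the list alone), with a median log2 fold change of 0.73. The mitotic cyclin Ccnb1 rose from 11.7 to 30.7 CPM (1.39 ± 0.20), Cdc20, an activator of the anaphase-promoting complex, by 1.42 ± 0.25, the checkpoint kinase gene Bub1b by 1.16 ± 0.22 and the tubulin-binding Stmn1 by 0.87 ± 0.16. The camera adjusted p was 4.04e-12, with an adjusted p of 0.32 with an estimated correlation. Relative to the pan-macrophage markers the list's mean differed by 0.00 ± 0.13 (exact permutation test, two-sided p = 0.9).

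Among inflammatory genes, Il1b, which encodes interleukin-1 beta, rose from 407 ± 102 to 872 ± 221 CPM (log2 fold change 1.10 ± 0.22, edgeR adjusted p = 0.00965). Other cytokine and chemokine genes fixed beforehand did not pass the test: the log2 fold change was 0.87 ± 0.35 for Il6, 0.57 ± 0.19 for Tnf, 0.43 ± 0.19 for Ccl2 and 0.52 ± 0.23 for Cxcl2, with edgeR adjusted p-values of 0.128, 0.0755, 0.169 and 0.171. Il6 was called with the GC correction (0.0289) and Tnf without the low-count filter (0.0393). Nlrp3, the inflammasome sensor, had 0.58 ± 0.26 (edgeR adjusted p = 0.176). In the inflammasome list 4 of 16 genes rose and 0 fell (7 adjusted over the list alone; median 0.52): Il1b, the protease gene Casp1 (0.64 ± 0.14), Nlrp1a (0.77 ± 0.20) and the adaptor Pycard (0.51 ± 0.14). In the NF-kB list 7 of 24 rose, with Nfkbid at 0.82 ± 0.14, Birc3 at 0.60 ± 0.12, Ptgs2 at 1.30 ± 0.29 and Traf1 at 0.64 ± 0.16, and 1 fell, Tnfaip2 (median 0.49; 10 rose and 1 fell adjusted over the list alone). Immediate-early and heat-shock genes, which respond to tissue digestion, showed 7 of 30 higher and 0 lower (14 adjusted over the list alone; median 0.51), with Egr2, Klf6, Dusp1 and Atf3 at 0.83 ± 0.15, 0.56 ± 0.14, 0.73 ± 0.18 and 0.69 ± 0.18. With single libraries left out, calls were lost by Pycard in 5 of 6 fits (edgeR adjusted p from 0.058 to 0.122), by Nlrp1a, Traf1, Klf6 and Atf3 in 4, by Dusp1 in 3 and by Casp1 and Tnfaip2 in 2. Camera adjusted p-values of these 3 lists were 0.000184, 4.18e-06 and 2.72e-06, each with an adjusted p of 0.32 with an estimated correlation. Relative to the pan-macrophage markers the 3 lists differed by -0.26 ± 0.08, -0.26 ± 0.12 and -0.30 ± 0.16, and Il1b by 0.38 ± 0.24 (exact permutation test, two-sided p = 0.1, 0.2, 0.2 and 0.2).

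The cytokine and chemokine lists as wholes were not called by camera in this fit. Of 20 cytokine genes 5 rose, with Osm at 1.05 ± 0.19, Ebi3 at 0.76 ± 0.15 and Tnfsf9 at 0.85 ± 0.18 besides Il1b, and 2 fell, Il33 (-3.15 ± 0.32) and the macrophage growth factor Csf1 (-2.49 ± 0.27). Of 23 chemokine genes 3 rose, Ccl12, Cxcl16 and Ccl6 (0.89 ± 0.18, 0.54 ± 0.12 and 0.70 ± 0.18), and 3 fell, Ccl11, Cxcl14 and Cx3cl1 (-2.16 ± 0.22, -2.62 ± 0.30 and -1.40 ± 0.26). The fibroblast markers, for comparison, had a median of -3.03. Relative to the pan-macrophage markers the 2 lists differed by -0.64 ± 0.17 and -0.60 ± 0.21 (exact permutation test, two-sided p = 0.1 each). These are differences of means, which the falling members lower. The lists had median log2 fold changes of 0.56 and 0.43 and means of 0.02 and 0.27. Adjusted over the list alone, 10 cytokine genes rose and 4 fell, and 4 chemokine genes rose and 4 fell. The camera adjusted p was 0.0512 and 0.109. Both lists were called in several other settings, among them no low-count filter (0.0286 and 0.0313) and 3 of the 6 fits with a library left out.

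The 3 subset markers fixed beforehand did not pass the test. The resident marker Timd4 differed by 0.05 ± 0.25 (15.9 ± 2.05 and 15.4 ± 4.90 CPM, edgeR adjusted p = 0.927) and Lyve1 by 0.35 ± 0.14 (edgeR adjusted p = 0.116). Ccr2, the receptor of recruited monocytes, differed by 0.87 ± 0.29 (edgeR adjusted p = 0.0733, and 0.0389 with the GC correction). In the resident list 6 of 25 genes rose, among them the complement genes C1qa, C1qb and C1qc (0.62 ± 0.15, 0.78 ± 0.16 and 0.80 ± 0.18) and Ltc4s (0.66 ± 0.14), and 1 fell, Cd209b (-2.41 ± 0.56); the median was 0.37, below that of the pan-macrophage markers. In the monocyte list 8 of 26 rose, with Napsa, Gpr141 and Cd52 at 1.16 ± 0.19, 0.90 ± 0.20 and 0.73 ± 0.16 besides Ms4a4c, and 3 fell, Vcan (-3.35 ± 0.32), S100a6 (-0.94 ± 0.15) and Thbs1 (-1.69 ± 0.31). Adjusted over the list alone, 11 resident genes rose and 1 fell, and 9 monocyte genes rose and 4 fell. The camera adjusted p was 4.08e-05 for the resident list (adjusted p = 0.327 with an estimated correlation) and 0.0512 for the monocyte list. Relative to the pan-macrophage markers, the resident list differed between Tet2 KO and Tet2 WT by -0.42 ± 0.05 and the monocyte list by -0.66 ± 0.14 (exact permutation test, two-sided p = 0.1 each). These are differences of means. The monocyte list had a median log2 fold change of 0.45 and a mean of 0.11, lowered by members such as Vcan. Whether the fall of Vcan arose in macrophages or from a smaller share of fibroblast RNA cannot be told here.

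**Figure D4:**
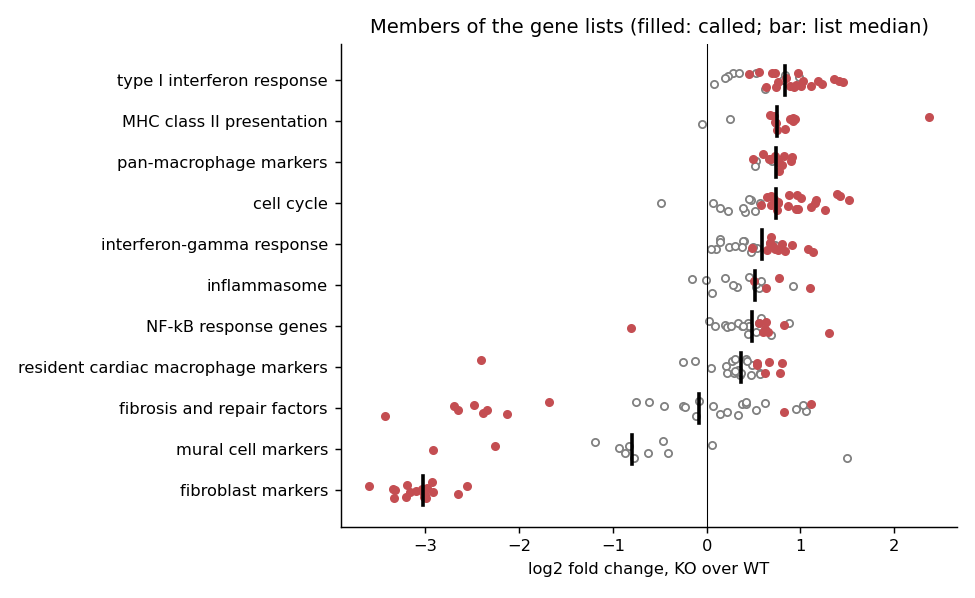
Log2 fold change of each tested member of 11 gene lists (1 point per gene, filled where called, black bar at the list median). The fibroblast markers have a median of -3.03, and the type I interferon, MHC class II, cell cycle and pan-macrophage lists lie together between 0.73 and 0.83.

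Further macrophage lists rose by camera at adjusted p-values of 0.00124 (alternative activation), 0.000716 (efferocytosis and lysosome), 0.0073 (complement and Fc receptors) and 0.00504 (antioxidant and haem-iron handling), each with an adjusted p of 0.32 with an estimated correlation. Of 23 alternative-activation genes 8 rose, among them Egr2, the lectin genes Cd209a and Mgl2 (0.80 ± 0.16 and 0.81 ± 0.17) and Pdcd1lg2, at 0.566 CPM in Tet2 KO and 0.012 in Tet2 WT, and 2 fell, Socs2 and Tgm2. Of 28 efferocytosis genes 8 rose, with Havcr2, Dock2 and Lgmn at 0.73 ± 0.12, 0.73 ± 0.14 and 0.77 ± 0.16, and 2 fell, Mfge8 and Lrp1. Of 21 complement and Fc receptor genes 11 rose, with Fcgr4 at 0.98 ± 0.14 and Cfp at 1.02 ± 0.22, and 3 fell, C3 (-2.72 ± 0.23), Cd55 (-3.12 ± 0.41) and C4b (-0.54 ± 0.15). Of 20 antioxidant and iron genes 4 rose, including Slc11a1 (0.64 ± 0.15) and Trf (0.81 ± 0.20), and 0 fell. Adjusted over the list alone, the rises numbered 10, 16, 13 and 9 and the falls 2, 4, 4 and 1. Set against the pan-macrophage markers, these 4 lists differed between Tet2 KO and Tet2 WT by -0.30 ± 0.08, -0.51 ± 0.14, -0.70 ± 0.10 and -0.46 ± 0.09 (exact permutation test, two-sided p = 0.1 each). Their median log2 fold changes were 0.53, 0.36, 0.62 and 0.38. Differences of means also take in members that fell strongly. The complement list, with C3 and Cd55, had a mean log2 fold change of 0.10. Whether C3 and Cd55 fell in macrophages or through a smaller share of fibroblast RNA cannot be told here.

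Fibrosis and repair factors went both ways. Of 29 genes 8 fell, led by the matricellular Ccn2 (-3.43 ± 0.19), Sparc, Mmp14 (-2.13 ± 0.24) and the angiogenic factor Vegfa (-2.34 ± 0.27), and 2 rose, the collagenase Mmp13 (1.11 ± 0.15) and Lgals3 (0.83 ± 0.18); 10 fell and 2 rose adjusted over the list alone. The median was -0.09, the mean -0.49 and the camera adjusted p 0.109, while fry called the list lower (adjusted p = 0.0103). Sparc also belongs to the fibroblast list, whose median was -3.03. These libraries cannot tell whether the falls arose in macrophages or from a smaller share of fibroblast RNA. DNA methylation enzymes were not called as a list (camera adjusted p = 0.339): of 21, Mbd2 (1.79 ± 0.49) and Dnmt3a (0.46 ± 0.14) rose, and Dnmt3l and Gadd45a (-4.45 ± 0.86 and -1.23 ± 0.26) fell. Dnmt3l was at 0.086, 0.175 and 0 CPM in Tet2 KO and averaged 1.95 CPM in Tet2 WT, so its fold change rests on almost no Tet2 KO counts. Mbd2 was at 68.1, 13.5 and 53.1 CPM in Tet2 KO and at 12.02, 12.8 and 14.1 CPM in Tet2 WT, so its libraries overlapped. Mbd2 and Dnmt3a lost their calls in several settings. Among them were no low-count filter (edgeR adjusted p = 0.236) and the stricter filter (0.0504) for Mbd2, and RLE scaling for Dnmt3a (0.0549). Adjusted over the list alone, 2 rose and 3 fell.

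Markers of other cells differed less than those of fibroblasts. The mural cell list was lower (median -0.80, camera adjusted p = 0.00504, adjusted p = 0.327 with an estimated correlation), with 2 of 12 genes lower, Pdgfrb (-2.92 ± 0.31) and Abcc9 (-2.26 ± 0.38), and its call was lost without Tet2 KO replicate 3 (0.0726). The erythroid list was higher (median 2.01, camera adjusted p = 0.00259, adjusted p = 0.327 with an estimated correlation). Of its 6 genes only Alas2 was called; Hba-a1, an alpha globin, stood at 99.8 CPM in Tet2 KO and 22.2 CPM in Tet2 WT (edgeR adjusted p = 0.0868). Of 18 endothelial genes 3 fell, Tek, Ly6c1 and Eng (-2.59 ± 0.21, -0.99 ± 0.21 and -0.64 ± 0.18), and the list was not called (camera adjusted p = 0.839). Of 11 B cell genes Cd79b, Bank1 and Ighm rose and Ebf1 fell (-2.41 ± 0.23; camera adjusted p = 0.157). Cardiomyocyte markers (0 of 20 called), T and NK cell markers (0 of 12), neutrophil markers (3 of 10 higher) and dendritic cell markers (2 of 17 higher, 2 lower) were not called as lists by camera, with adjusted p-values of 0.851, 0.256, 0.0851 and 0.157. Fry called the neutrophil and B cell lists higher (adjusted p = 0.0401 and 0.0299), and camera called the neutrophil list with the stricter filter (adjusted p = 0.0136). Adjusted over the list alone, 2 mural, 3 endothelial and 1 B cell and 2 dendritic cell genes fell, and 3 erythroid, 3 B cell, 3 neutrophil and 3 dendritic cell genes rose. Only 3 mast cell genes were tested, with 0 called. The 4 sex-linked genes tested showed 0 calls, and the Y-linked Ddx3y stood at 84.3 CPM in Tet2 KO and 86.3 CPM in Tet2 WT.

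Among measures of RNA quality and metabolism, mitochondrially encoded genes took 5.49 ± 2.61% of counts in Tet2 KO and 7.62 ± 1.20% in Tet2 WT (exact permutation test, two-sided p = 0.3), with Tet2 KO replicate 1 at 2.83%. That list was lower by camera with the preset correlation (median -0.36, adjusted p = 0.0300) and had an adjusted p of 0.604 with an estimated correlation, with 0 of 13 genes called. Its call was lost with the GC correction (0.274), without Tet2 KO replicate 1 (0.558), without Tet2 WT replicate 1 (0.0874) and without Tet2 WT replicate 2 (0.0711). Ribosomal protein genes (0 of 44 called, median -0.14) and nuclear oxidative phosphorylation genes (0 of 40 called, median 0.07) were not called, with camera adjusted p-values of 0.0709 and 0.109, although the ribosomal list was called lower with the GC correction (0.0264). Neither were the cholesterol (2 of 24 lower), glycolysis and hypoxia (5 of 26 higher, 4 lower) and lipid-associated macrophage lists (6 of 22 higher, 4 lower), with 0.887, 0.0802 and 0.0512. At equal depth, 19284 ± 976 genes were detected in Tet2 KO and 20512 ± 885 in Tet2 WT (exact permutation test, two-sided p = 0.3). In all, 17 of 33 lists were called by camera with the preset correlation, 14 higher and 3 lower; with an estimated correlation 0 were called, with 2 at an unadjusted p under 0.05, and fry called 10 higher and 2 lower. Of the 17, fry did not call the NF-kB, immediate-early, resident, alternative activation, complement, mural cell, erythroid and mitochondrially encoded lists (adjusted p from 0.0593 to 0.389).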

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

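Of the settings below, scaling to the pan-macrophage markers, the fibroblast covariate and the removal of Tet2 WT replicate 1 with Tet2 KO replicate 1 were chosen after seeing the data. With each library left out in turn, the called genes ranged from 1382 to 3141, those higher in Tet2 KO from 350 to 1402 and those lower from 1032 to 1739; the lowest values came without Tet2 WT replicate 1. Called lists ranged from 16 to 21 (14 to 18 higher, 2 to 4 lower), and the Tet2 log2 fold change from 0.25 to 0.46. Timd4 ranged from -0.18 to 0.22 and Tet3 from -0.13 to 0.42. The difference in total estimated counts (KO minus WT, in units of 1e6) ranged from -6.15 to 3.01 that in summed mast cell CPM from -2.61 to 0.68, that in the mitochondrially encoded percentage from -3.41 to -0.80 and that in genes detected at equal depth from -1767 to -717. Limma voom with library weights called 4045 genes, 1806 of them higher. Limma on log2(TPM + 1) called 384 higher genes and gave Timd4 -0.0618; on log2(TPM + 0.1) it called 400 and gave Timd4 -0.0624. Length-scaled TPM counts gave Tet2 0.43 with an edgeR adjusted p of 0.0458; over all settings Tet2 adjusted p-values ran from 0.0458 to 0.999. Camera with an estimated correlation called 0 lists (0 higher, 0 lower), with 2 at an unadjusted p under 0.05, and fry called 12. Camera called 24 lists without the low-count filter and 20 each with RLE scaling and the stricter filter, against 17. The cytokine, monocyte and lipid-associated lists were called with RLE scaling, without the filter and in 3 leave-one-out fits each, and the chemokine list without the filter and in 3 leave-one-out fits. The ribosomal protein list was called without the filter, with the stricter filter, with the GC correction, with length-scaled TPM counts, with library weights and in 2 leave-one-out fits. The glycolysis and oxidative phosphorylation lists were called without the filter and in 2 and 1 leave-one-out fits, the neutrophil list at equal depth and in 1, and the endothelial and dendritic cell lists in 1 each. The cause of these shifts was not tested. Over the planned settings, the values of the 130 other named genes stayed on the same side of the threshold with the same sign 2625 times, lost the call 203 times, gained it 26 times and changed sign 5 times. Losses were 7 without the low-count filter, 4 to 30 in leave-one-out fits (most without Tet2 WT replicate 1), 20 with log2(TPM + 1) and 18 with log2(TPM + 0.1). Limma voom called Tet1 and Hba-a1, and DESeq2 called Tet1, Tnf, Ccr2 and Hba-a1; voom with library weights called Tet1, Ccr2, Lyve1 and Hba-a1.

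Scaled to the pan-macrophage markers, 7620 genes were called, 21 higher and 7599 lower, since this scaling moves the median of all genes by -0.71. The log2 fold change then became -0.38 for Tet2, -0.49 for Tet3, -0.12 for Tnf, -0.28 for Ccl2, -0.16 for Cxcl2, -0.10 for Nlrp3, -0.63 for Timd4, -0.36 for Lyve1, -0.18 for Cxcl16, -0.075 for Casp1, -0.20 for Pycard, -0.10 for Birc3, -0.057 for Traf1, -0.15 for Klf6, -0.0070 for Atf3, -0.076 for C1qa, -0.040 for Ltc4s, -0.058 for Slc11a1, -0.25 for Dnmt3a and -0.073 for Bank1. The nuclear oxidative phosphorylation list turned to lower by camera (adjusted p = 0.0088).

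With the fibroblast level as a covariate, edgeR called 0 genes (0 higher, 0 lower; 649 at an unadjusted p under 0.05) and limma voom 0 (964 at an unadjusted p under 0.05). Genotype and fibroblast level had a correlation of -0.93 over these libraries by their grouping, so that fit has little room to tell them apart. Camera then called 9 lists, 6 higher. The log2 fold change became -0.28 for Tet2, -0.46 for Tet3, -0.042 for Tnf, -0.30 for Cxcl2, -0.24 for Nlrp3, -0.97 for Timd4, 0.49 for Comp, 0.014 for Cx3cl1, -0.13 for Ptgs2, -0.088 for Cd52, 0.45 for Thbs1 and -0.71 for Pdcd1lg2. The NF-kB, resident, alternative activation and complement lists turned direction with camera adjusted p-values of 0.889, 0.223, 0.482 and 0.984. Without Tet2 WT replicate 1 and Tet2 KO replicate 1 together, 1188 genes were called, 177 higher and 1011 lower, Timd4 was -0.10, and the mitochondrially encoded list turned to higher (camera adjusted p = 0.777).

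The replicate numbers are not stated to mark a shared animal or day. The deviations of same-numbered libraries from their genotype's mean correlated at 0.06, 0.13 and 0.04. In all, 6 of 6 libraries correlated best with their own number, a weak hint from the data and not from the design. Centring on the mean of 3 libraries makes these matches depend on one another. With the replicate number as a block, 2347 genes were called (789 higher, 1558 lower), and 2259 with the GC correction added. Camera with the block called the cytokine, chemokine and ribosomal protein lists (adjusted p = 0.0154, 0.0214 and 0.0179), and with the GC correction added it lost the mitochondrially encoded list (0.262); of the named genes 14 lost and 2 gained a call with the block. With 3 libraries per group and 200 changed genes, the simulated data gave calls for 6% of changes of 1.5-fold and 50% of 2-fold. The real fit called 2653 genes, which loosens the adjusted threshold, so these percentages do not give its power. Small changes may still be missed.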

Other observations

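The tests of dilution, both tests of Tet2 and the extended line through the Tet2 WT libraries, with their bounds, were chosen only after the result was seen; the 2 further fibroblast lists were chosen after the main result but before their own values were seen.

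A small set of genes stayed higher when libraries were scaled to the pan-macrophage markers. Of 7620 genes called under that scaling, 21 were higher in Tet2 KO, 5 of them processed pseudogenes. The adjusted p-values limit false calls over all 7620 genes and not among the 21. The share of false calls among the 21 may therefore be well above 5%. Others included the interferon genes Irf7 (log2 fold change 0.69 ± 0.26, edgeR adjusted p = 0.0471) and Ifi206 (1.11 ± 0.21, edgeR adjusted p = 0.00209), the mitotic genes Ccnb1 (0.69 ± 0.22) and Cdc20 (0.71 ± 0.26), and Gdf3 (1.22 ± 0.26), Parvg (0.74 ± 0.18), Ms4a4c (0.73 ± 0.25) and Alas2 (1.91 ± 0.48). Alas2 belongs to the erythroid list, so its rise need not come from macrophages. Il1b was at 0.43 with an edgeR adjusted p of 0.0898. Over all settings the Il1b log2 fold change ran from 0.00 to 1.33.

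The lower fibroblast genes in Tet2 KO extended beyond the collagens. Among 20 fibroblast transcription factors and receptors, 17 were lower and 0 higher, including Tbx20 (-3.20 ± 0.36), Gata4 (-3.15 ± 0.38), Prrx1 (-2.79 ± 0.32) and the collagen receptor Ddr2 (-2.79 ± 0.19), while Cdh11, Axl and Thy1 were not called. Among 20 other fibroblast genes 19 were lower, with a median of -2.92, and Col14a1 was not called. The abundant members of the marker list itself, Gsn and Dcn, stood at 2274 ± 745 and 693 ± 249 CPM in Tet2 KO and at 13402 ± 4157 and 5241 ± 1557 CPM in Tet2 WT; as members they give its level and add no separate support. Of the 18 fibroblast markers 1 (Sparc) also belongs to another list, as do 2 of the 20 transcription factors and receptors (Axl and Pdgfrb) and 0 of the other 20. At 1 CPM or more in Tet2 KO were 18, 15 and 20 genes of these lists, so none is silent there as a whole.

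The first pattern is the fall of fibroblast genes in the Tet2 KO libraries. A smooth GC trend over all genes is argued against, since the marker median stayed at -3.07 after a GC correction. At equal depth the median was -3.02. Thinning hardly moves a CPM ratio of well-counted genes, so that value decides little about depth. More fibroblast RNA in the Tet2 WT libraries is consistent with the median of -2.79 for the transcription factors and receptors; a macrophage sort should remove fibroblasts, and its gate is not given in the sources used here. Lower expression by the Tet2 KO macrophages themselves stays open: a line through the 3 Tet2 WT libraries, extended to the Tet2 KO fibroblast level, met the observed pan-macrophage CPM at a mean ratio of 1.02 (1.12, 0.916 and 1.02 per library, against a bound of 10%), and with 1 residual degree of freedom its limits were 0.717 to 1.76. If macrophages and fibroblasts were the only RNA sources, the marker ratios would need about 35.8% fibroblast RNA in Tet2 WT and 3.93% in Tet2 KO, and a biological cause of such a difference in the hearts was not tested.

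The second pattern is the rise of macrophage lists in the Tet2 KO libraries, for which dilution of macrophage RNA by fibroblast RNA in Tet2 WT is a candidate explanation. Relative to the pan-macrophage markers of the same libraries, the MHC class II list differed by 0.062 ± 0.046, the cell cycle list by 0.0028 ± 0.13 and the NF-kB list by -0.26 ± 0.12, so that, within 2 standard errors, under 50% of each rise exceeded that of these markers. Dilution needs this, but an effect of genotype that raised all macrophage genes alike would meet it too and was not tested. The bound covers only an excess. The resident, complement and efferocytosis lists differed by -0.42 ± 0.05, -0.70 ± 0.10 and -0.51 ± 0.14. The antioxidant, alternative activation and inflammasome lists differed by -0.46 ± 0.09, -0.30 ± 0.08 and -0.26 ± 0.08. Interferon-gamma was at -0.17 ± 0.16. Equal dilution of every member gives about 0, as does an equal rise. Members whose RNA fibroblasts also hold would be diluted less, which gives values below 0. Scaled to the pan-macrophage markers, the median of all tested genes likewise moved by -0.71. Values below 0 therefore do not argue against dilution. Falling members such as C3 lower some means. For the type I interferon list (0.039 ± 0.22) and Il1b (0.38 ± 0.24) the spread over 3 libraries is too wide, and dilution and an effect of genotype cannot be told apart.

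The third pattern is that Tet2 counts were not lower in the Tet2 KO libraries. A swap of 1 Tet2 KO label with 1 Tet2 WT label was examined as a way to hide a halving of Tet2. Over the 9 possible exchanges the lowest log2 difference in CPM would be -0.022, and no 95% limit lay below -0.59. All 6 libraries lay between 57.5 and 82.6 CPM of Tet2, so no exchange could have given a halving. The outcome restates that range. A smaller fall is not excluded, and gene-level counts do not test whether the labels are right. Reads from a disrupted Tet2 transcript may still be counted, but ENSMUST00000197211.1, at 0 in Tet2 KO, had as few as 6.69 counts in a Tet2 WT library, below the 20 asked for, which leaves this open.

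The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. Each other split mixes the genotypes in both groups, so the genotype difference adds to the spread within groups and makes gene calls unlikely. Their groups still differ in genotype share, so their called lists do not measure false calls. By edgeR the real split gave 2653 genes (4734 at an unadjusted p under 0.05) and the highest of the others 0, so 1 of 10 splits gave as many. The other splits had 103 to 806 genes at an unadjusted p under 0.05, and limma voom called 2836 genes for the real split and 0 for each of the others. For lists, the real split gave 17 and the highest of the others 21, and 4 of 10 splits gave at least 17, the real split included.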
